A study of Mus musculus with 21 samples.

How the data were processed

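RNA was measured by sequencing in 21 libraries of T cells from Foxp3-GFP mice at 8 weeks of age and 7 days after myocardial infarction. The libraries fall into 7 groups of 3: regulatory T cells (Tregs) of heart, spleen, non-draining lymph node (NDLN) and mediastinal lymph node (MLN, which drains the heart), and conventional T cells (Tconvs) of heart, spleen and NDLN. Group and replicate number were taken from the library titles. Per the labels' protocols, cells were enriched with magnetic beads, sorted by flow cytometry into lysis buffer and made into libraries with a SMARTer kit for very small amounts of RNA. The labels do not say that replicates came from separate animals, so every p-value here measures the spread between these libraries, which can be partly technical.

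The values used are the count of reads per gene as deposited by the authors, whole numbers that are not normalized. Per the submitters' processing notes, the tools were CASAVA 1.8.2, HISAT2 and HTSeq 0.6.0 and the genome build was mm10; the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The table holds 49510 genes by Ensembl ID and 21 columns, each matched by its name to a single library, and 0 columns were left unused. Of the IDs, 49326 were found in the annotation names for GENCODE M21. In 26 genes a symbol that a spreadsheet had turned into a date was restored from the ID, and 168 genes share a symbol with another gene. Positions are given on GRCm38, the assembly that mm10 stands for, from GENCODE M21, counted from 1.

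Genes were kept by edgeR's filterByExpr with the group as factor (minimum count 10, minimum total 15), which left 14996 genes. Counts were scaled with TMM factors, and levels of genes are TMM-scaled CPM, counts scaled to a common library size, as mean ± SD over 3 libraries. Summed levels of lists are CPM of the library total without the TMM factors, which ran from 0.798 to 1.35. All 21 libraries entered a single edgeR 4.0.16 fit in R 4.3.3 with a coefficient per group, so that the 7 groups share their estimate of the spread. Contrasts were tested with the quasi-likelihood F-test with robust estimation and Benjamini-Hochberg adjustment, and genes were called at an adjusted p under 0.05. Standard errors (SE) were derived from the log2 fold change and the F statistic. Of the contrasts, 9 set a pair of groups against each other, and a further pair ask whether the difference between Tregs and Tconvs in heart departs from that in spleen or in NDLN. The heart Treg signature holds the genes called in the same direction against each of the lymphoid Treg groups, and the shared Treg signature those called in the same direction in Tregs against Tconvs of heart, spleen and NDLN. Groups, contrasts, tests, gene lists and most repeat settings were fixed before the data were examined.

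A total of 27 gene lists with 400 entries were tested in each contrast with camera of limma 3.58.1 on log-CPM (prior count 2) with its preset correlation of 0.01, adjusted over the lists within a contrast. Camera asks whether the members of a list lie higher or lower than the other genes. Beside this stand the adjusted p with an estimated correlation between members, and the number of members called over all genes tested and adjusted over the list alone. Where no number of called members is given, none passed over all genes tested: of 112 called list tests, 71 had 0 members called by edgeR, while of their 960 members tested 295 had an unadjusted p under 0.05, 223 were called by DESeq2 and 102 by limma-voom. No called list had a median or mean fold change of the opposite sign to its test. The 18 programme lists are Treg identity, tissue-repair Treg, suppressive effector, naive and lymphoid homing, tissue homing and adhesion, immediate early and TCR activation, heat shock, TNF receptor and costimulation, cell cycle, repair and growth factors, Th1, Th2, Th17, Tfh, interferon response, glycolysis, hypoxia and lipid handling. The 9 lists of other cell types are fibroblast, cardiomyocyte, endothelial, macrophage and monocyte, neutrophil, dendritic cell, B cell, CD8 and NK cell, and erythroid. The lists share genes. In the Treg identity list 7 of 21 members stand in another list as well, in the tissue-repair Treg list 11 of 19 and in the suppressive effector list 8 of 16.

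The genes named follow a rule fixed with the design. In each contrast it takes the 6 called genes with the highest and the 6 with the lowest log2 fold change among those with at least 20 CPM in the higher group and no overlap between the libraries of the groups. Predicted genes, ribosomal protein genes and immunoglobulin or T cell receptor segments are left out, the interactions drop the overlap condition, and the signatures rank by the smallest fold change over the 3 contrasts. From each list described it adds up to 4 members with the smallest adjusted p and members that did not pass. It also adds Foxp3, Il2ra, Cd4, Cd3e, Sparc, Areg, Il1rl1, Ctla4 and Ccr7 whatever their result, and genes whose difference departed between tissues. Some genes that the rule takes are not reported here.

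Totals ran from 14515387 to 28323649 counts per library, so that 3 counts correspond to 0.11 to 0.21 CPM. Where all 3 libraries of a group had 0 counts, a fold is printed as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts over the group, the ratio is printed with its 95% counting interval. Floors and intervals cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. Reads cannot be told apart with certainty between Ctla2a and its paralog Ctla2b, between Fth1 and its pseudogenes, or between mt-Nd6 and the genes on the opposite strand, so those values are uncertain.

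The steps were tested on simulated counts drawn from the means, spreads and library sizes of the real libraries. Among 14996 genes, 100 of at least 20 CPM were changed 8-fold. Of these, 34 were called for heart against spleen Tregs, 24 for heart Tregs against heart Tconvs and 43 for NDLN Tregs against NDLN Tconvs. Of 100 such genes changed 32-fold the numbers were 64, 60 and 65. The comparisons were repeated with median-of-ratios scaling, with DESeq2 1.42.0, with limma-voom and sample quality weights, without a filter (26527 genes), with a stricter filter of at least 5 CPM in at least 3 libraries (11380 genes), with the replicate number as a block, with only the groups compared in the fit, and without each library in turn. After the data had been seen, fits with the library set described in the results as a covariate and with its 16 or 5 libraries alone were added. So were shared genes at an unadjusted p and among the 1000 genes of smallest p.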

Results

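T cells of mice were profiled 7 days after myocardial infarction, the death of heart muscle that follows the loss of its blood supply. The mice were 8 weeks old and carried Foxp3-GFP, a green fluorescent reporter of the gene that defines regulatory T cells (Tregs), by which Tregs were sorted from conventional T cells (Tconvs). The 21 libraries form 7 groups of 3: Tregs of the injured heart, the spleen, a non-draining lymph node (NDLN) and the mediastinal lymph node that drains the heart (MLN), and Tconvs of heart, spleen and NDLN. Per library, 9469 to 16239 genes had at least 1 count. No pair of replicates agreed within sampling noise, and their log-CPM correlated with Pearson's r of 0.663 to 0.804 across genes. The common dispersion was 2.19, a biological coefficient of variation of 1.48. Levels below are CPM as mean ± SD with n = 3, and each adjusted p is that of edgeR's quasi-likelihood test unless camera is named.

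The libraries fell into sets that cross the groups. Of 234 genes that were at or under 0.5 CPM in some libraries and at or above 5 CPM in all others, with at least 4 libraries on either side, 26 divided the libraries in the same way. On 1 side stood MLN Treg replicates 1 and 2, heart Treg replicate 1 and heart Tconv replicates 1 and 2 (5 libraries), and on the other the remaining 16. The next most frequent division had 3 genes. Celf1, an RNA-binding splicing regulator, and Ndufs3, a subunit of respiratory complex I, were among the 14 genes missing in the 5, and the ephrin receptor gene Epha7 was among the 12 missing in the 16. Mitochondrial ribosomal RNA took 0.0567 to 0.102% of counts in the 5 and 0.954 to 12.3% in the 16. Ribosomal protein genes took 4.61 to 9.22% against 10.6 to 24%, and all mitochondrial genes 0.956 to 1.77% against 2.88 to 17.2%. All spleen and NDLN libraries belong to the 16.

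**Figure D1:**
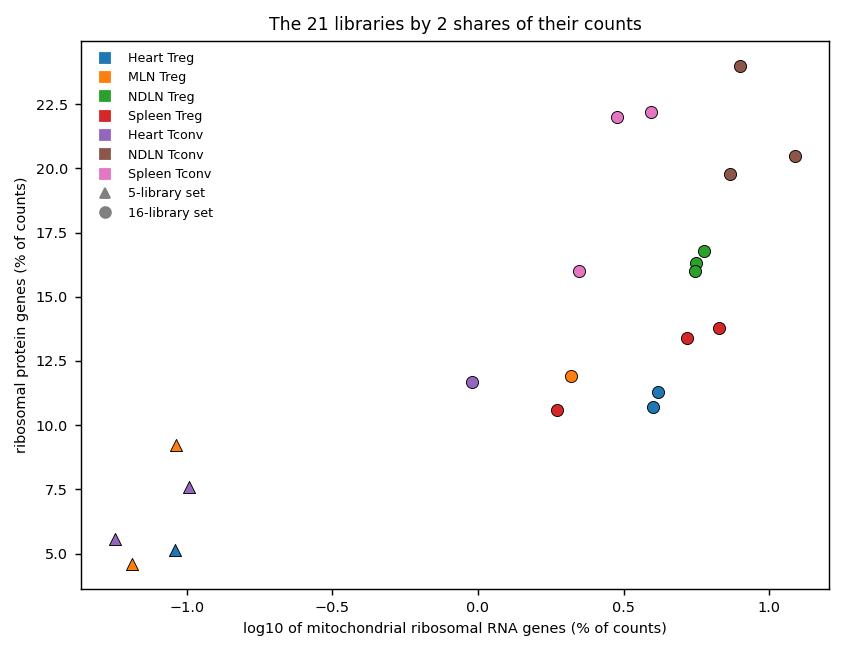
Each point is a library, placed by the share of counts from mitochondrial ribosomal RNA (x axis, percent, log10 scale) and from ribosomal protein genes (y axis, percent), coloured by group. Triangles mark the 5-library set. The 5 libraries lie at 0.0567 to 0.102% on the x axis and the other 16 at 0.954 to 12.3%.

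Transcripts of other cell types were present at group-dependent levels. Summed CPM (without TMM scaling) of the fibroblast list was 731 ± 433 in heart Tregs (259 in replicate 1), against 93.9 ± 32.3 in spleen, 73.7 ± 9.97 in NDLN and 75.7 ± 28.9 in MLN Tregs. In Tconvs it was 331 ± 95 in heart, 208 ± 44.4 in spleen and 180 ± 65.8 in NDLN. Of its 18 members, 3 reached 5 CPM in some lymphoid group, among them Thy1, which T cells express. The B cell list stood at 409 ± 130 in spleen Tregs, 287 ± 36.3 in NDLN Tregs and 107 ± 25.2 in MLN Tregs, and at 15 ± 12.9 in heart Tregs and 19.4 ± 27.4, 11.7 ± 15.6 and 1.26 ± 1.01 in heart, spleen and NDLN Tconvs. The erythroid list was uneven, at 23800, 1220 and 10400 in the spleen Treg and 342, 477 and 30100 in the MLN Treg libraries, and at 14.1 ± 14.8 in heart Tregs. The interferon response, cardiomyocyte and neutrophil lists were called in none of the contrasts by camera; for heart against spleen Tregs their adjusted p were 0.93, 0.75 and 0.25. Of their 20, 4 and 4 members tested there, edgeR called 0 in each, while 1, 0 and 2 had an unadjusted p under 0.05, DESeq2 called 1, 1 and 2, and limma-voom 0.

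**Figure D2:**
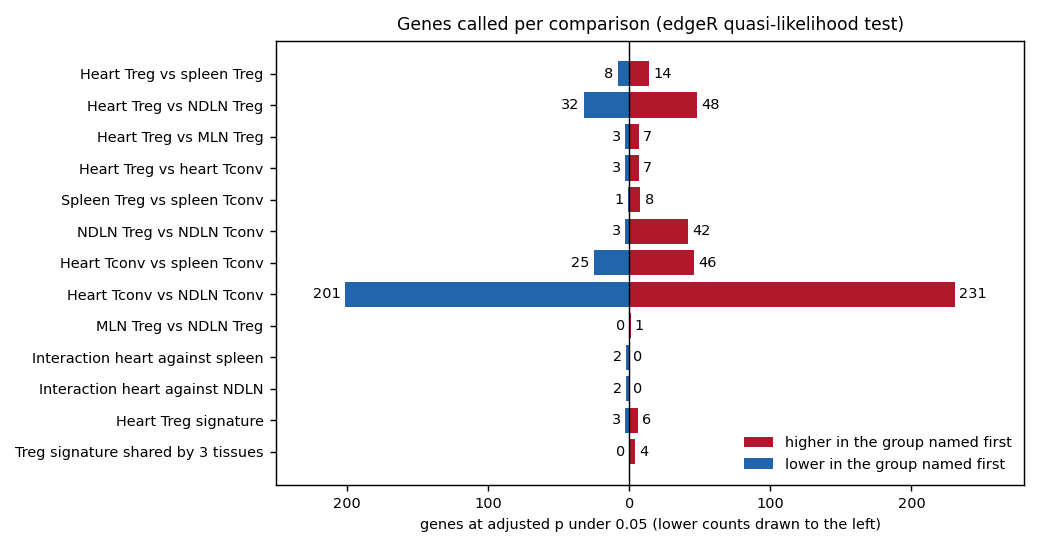
Bars give the number of genes called at an adjusted p under 0.05 in each comparison (x axis, genes), split into higher and lower. Heart Tconvs against NDLN Tconvs have the most, 231 higher and 201 lower, and MLN Tregs against NDLN Tregs a single gene.

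Tregs and Tconvs of the injured heart were compared to ask what sets Tregs apart at the site of damage. Foxp3, the transcription factor that defines Tregs (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand, protein coding), stood at 167 ± 71.1 CPM in heart Tregs and 0.0843 ± 0.0691 in heart Tconvs (log2 fold change 10.85, SE 0.94, adjusted p = 1.2e-05). Ikzf2, which encodes the Treg transcription factor Helios, was at 558 ± 228 against 34.9 ± 10.3 CPM, 16-fold higher (adjusted p = 0.00095). Ctla4, an inhibitory receptor that binds costimulatory ligands, was 9.97-fold higher (1660 ± 500 against 166 ± 40.7, adjusted p = 0.015). Lrrc32, whose product GARP holds latent TGF-beta on the Treg surface, had 58.5 ± 16.4 CPM in Tregs and 1 count over all heart Tconv libraries, a ratio of 4110 (95% counting interval 738 to 163000, adjusted p = 0.025). Lower in heart Tregs were Tcf7, a transcription factor of naive and memory T cells (16.5 ± 20.5 against 386 ± 248, 23.4-fold, adjusted p = 0.042), and H2-Aa, an MHC class II chain of antigen-presenting cells (ENSMUSG00000036594). H2-Aa had 3 counts over the heart Treg libraries and 177, 1.48 and 90.6 CPM in the heart Tconv libraries, a ratio of 2160 (738 to 10500, adjusted p = 0.015).

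Further genes higher in heart Tregs were the eotaxin receptor gene Ccr3 (93.6 ± 58.8 CPM, 1010-fold, adjusted p = 0.035) and the relaxin family gene Rln3 (45.3 ± 28.6 CPM, 715-fold, adjusted p = 0.035). Cep112, which encodes a centrosomal protein, was higher as well (11.1 ± 5.41 CPM against 1 count, ratio 760, 136 to 30100, adjusted p = 0.025). Sparc, which encodes a matrix-binding glycoprotein (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183), was at 103 ± 56.3 CPM in heart Tregs and 60.8 ± 52.6 in heart Tconvs, a difference smaller than its error (log2 0.76, SE 1.79, adjusted p = 1). Areg, a growth factor of tissue repair, did not pass (323 ± 239 against 63.5 ± 37.1, log2 2.35, SE 1.14, adjusted p = 0.6). Neither did Il1rl1, the IL-33 receptor gene (102 ± 55.8 against 6.68 ± 2.26, adjusted p = 0.6), nor Il2ra, the high-affinity IL-2 receptor gene (315 ± 111 against 32 ± 28.8, adjusted p = 0.63). Ccr7, which guides T cells into lymph nodes, stood at 792 ± 265 against 854 ± 258 CPM (adjusted p = 1).

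Among the lists, Treg identity had 19 of 21 members higher in heart Tregs, of which 4 passed over all genes tested and 7 adjusted over the list alone (camera adjusted p = 9.5e-16, and 0.00048 with an estimated correlation). The suppressive effector list had 13 of 15 higher, 1 called and 1 adjusted over the list alone (camera adjusted p = 2.1e-05). The cell cycle list had 22 of 23 members higher (camera adjusted p = 1e-07, and 0.051 with an estimated correlation). EdgeR and limma-voom called 0 of them and DESeq2 3, and 5 had an unadjusted p under 0.05. Mki67, a marker of dividing cells, was at 31.4 ± 6.21 against 19.8 ± 17.9 CPM (adjusted p = 1). The tissue-repair Treg list had 16 of 19 higher (camera adjusted p = 9.6e-06, and 0.051 with an estimated correlation). Lower in heart Tregs was the CD8 and NK cell list, 7 of 7 members (camera adjusted p = 0.00023, and 0.027 with an estimated correlation). So was the naive and lymphoid homing list, 12 of 15 with Tcf7 called (camera adjusted p = 0.016, and 0.08 with an estimated correlation). From the former, the granzyme gene Gzmk had 1 count over the heart Tregs and 128 ± 82 CPM in heart Tconvs (ratio 9480, 1700 to 375000, adjusted p = 0.32). The fibroblast list was higher in 13 of 14 members tested (camera adjusted p = 4.1e-08; adjusted p = 0.08 with an estimated correlation), though Col3a1, a fibrillar collagen gene, stood at 24.4 ± 21.8 and 21.2 CPM. Weaker calls were TNF receptor and costimulation (11 of 15 higher, adjusted p = 0.028), tissue homing and adhesion (12 of 21, 1 called, 0.028), repair and growth factors (0.041) and lipid handling (9 of 16, 0.045). Th1 (9 of 10, 0.026) and dendritic cell (5 of 7, with H2-Aa called, 0.026) were lower. With an estimated correlation these had adjusted p of 0.11, 0.27, 0.25, 0.25, 0.14 and 0.25.

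In all, 7 genes were higher and 3 lower in heart Tregs than in heart Tconvs by edgeR. DESeq2 called 239 higher and 742 lower, limma-voom 48 and 117. Heart Treg replicate 1 and heart Tconv replicates 1 and 2 belong to the 5-library set. The count was 17 within that set, which holds 1 heart Treg library, and 7 within the 16 (2 higher, 5 lower), which hold 1 heart Tconv library. A lone library is assumed to vary like the other groups. It was 31 without heart Treg replicate 1 (10 higher, 21 lower), 3 without heart Tconv replicate 1 and 6 without heart Tconv replicate 2. Foxp3 and Ikzf2 passed without any of the 6 libraries. H2-Aa was lost without heart Treg replicate 3 (adjusted p = 0.059) and Ctla4 without heart Tconv replicates 1 or 2 (highest 0.14). Of 8 named genes, 3 and 5 were lost without heart Treg replicates 2 and 3 and 5, 5 and 2 without heart Tconv replicates 1, 2 and 3 (highest adjusted p 0.32). Leaving out heart Treg replicate 1 ended 4 list calls, replicate 2 ended 1 and replicate 3 ended 2, and heart Tconv replicates 2 and 3 ended 3 and 4 (highest adjusted p 0.27, 0.15, 0.44, 0.19 and 0.12).

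**Figure D3:**
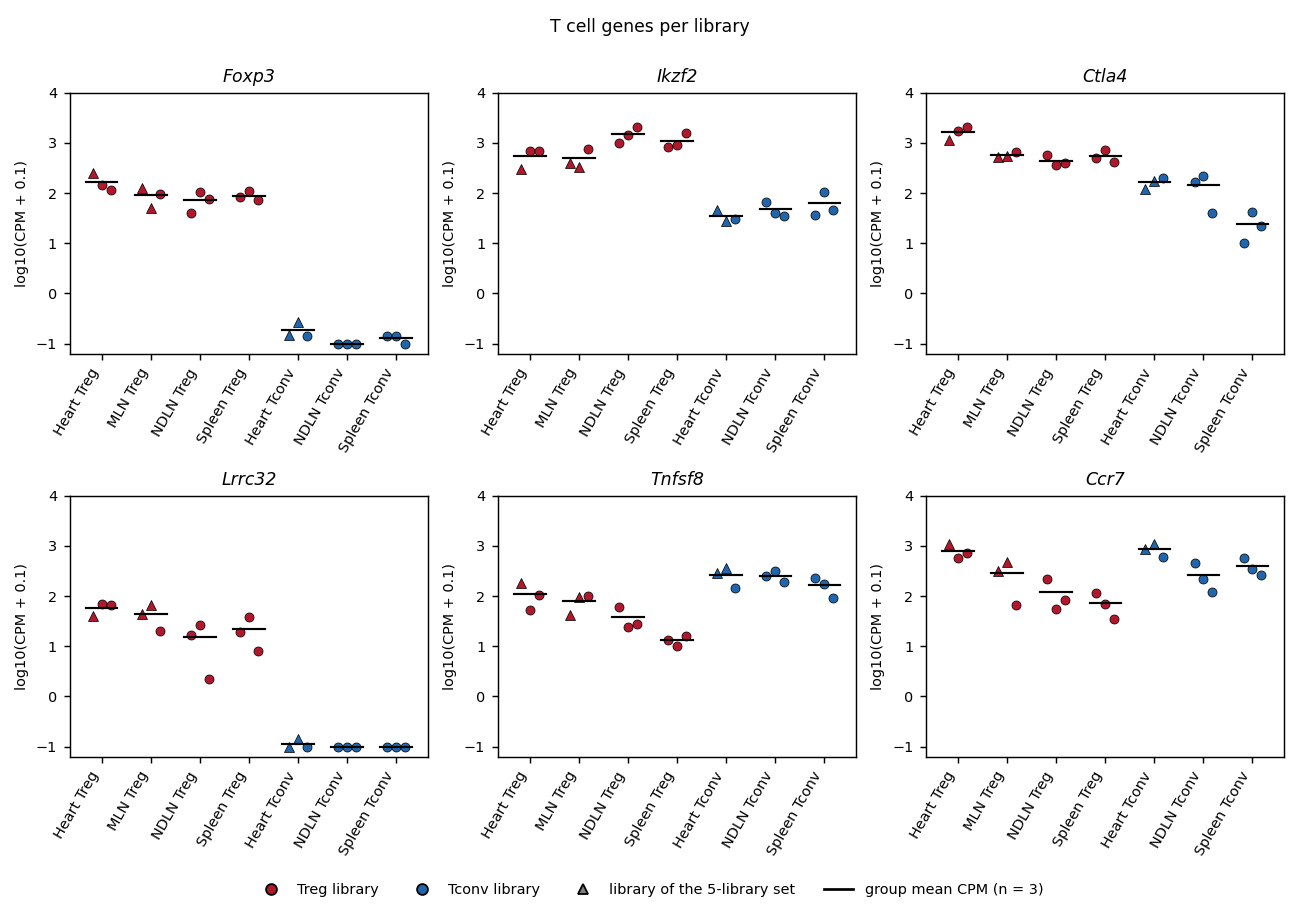
Levels of Foxp3, Ikzf2, Ctla4, Lrrc32, Tnfsf8 and Ccr7 in each library, as log10(CPM + 0.1) on the y axis, by group on the x axis; the lines are group means (n = 3) and triangles mark the 5-library set. Foxp3 means lie at 167 CPM in heart Tregs and 0.0843 in heart Tconvs, and Ikzf2 means at 558 and 34.9.

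In the spleen, Foxp3 was at 88.9 ± 18.7 CPM in Tregs and at 2 counts over the Tconv libraries (log2 fold change 11.31, SE 0.97, ratio 2980, 826 to 24600, adjusted p = 1.2e-05). Ctla4 was 22.4-fold higher in Tregs (547 ± 151 against 24.4 ± 15.7, adjusted p = 0.00043) and Ikzf2 17.7-fold (1110 ± 412 against 62.7 ± 37.2, adjusted p = 0.0004). Cep112 and Lrrc32 had 0 counts in spleen Tconvs and were at least 785-fold (36.1 ± 7.62 CPM, adjusted p = 0.0031) and at least 504-fold higher (21.6 ± 15.2 CPM, adjusted p = 0.023). Ccr3 had 58.5 ± 17.2 CPM in Tregs and 3 counts in Tconvs (ratio 1320, 450 to 6390, adjusted p = 0.03). The CD30 ligand gene Tnfsf8 was 12.8-fold lower in Tregs (13.1 ± 3.19 against 167 ± 71.6, adjusted p = 0.0059). Il2ra was at 235 ± 24.8 against 14.1 ± 22.7 CPM without passing (adjusted p = 0.62), and Ccr7 at 72.4 ± 38.7 against 393 ± 155 (adjusted p = 0.35).

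The Treg identity list was higher in 21 of 21 members in the spleen, 4 called and 12 adjusted over the list alone (camera adjusted p = 2.6e-27, and 2.1e-05 with an estimated correlation). The cell cycle list was higher in 23 of 23 members (camera adjusted p = 6.7e-12, and 0.0097 with an estimated correlation). Of these, 0 were called by edgeR (7 at an unadjusted p under 0.05, 6 by DESeq2, 3 by limma-voom) and 3 passed adjusted over the list alone. Mki67 was at 117 ± 101 against 14 ± 14.6 CPM (adjusted p = 0.62). The tissue-repair Treg list (18 of 19 higher, 10 higher and 1 lower adjusted over the list alone, camera adjusted p = 6e-14, and 0.0016 with an estimated correlation) rose as well. So did the suppressive effector list (13 of 15, 1 called and 7 adjusted over the list alone, 7.6e-11, and 0.0016). The naive and lymphoid homing list was lower in 12 of 15 members, 5 adjusted over the list alone (camera adjusted p = 2.2e-06, and 0.0024 with an estimated correlation). Its Lef1 and Tcf7, transcription factors of naive T cells, were at 80.7 ± 30.7 against 317 ± 92 (adjusted p = 0.4) and 29.7 ± 20.7 against 202 ± 43.6 CPM (adjusted p = 0.41). TNF receptor and costimulation was higher in 12 of 15, with 1 called, lower, and 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.004, and 0.042 with an estimated correlation). In it Tnfrsf18, the GITR gene, stood at 1050 ± 407 against 182 ± 35 CPM (adjusted p = 0.069). The B cell list was higher in spleen Tregs in 8 of 8 members tested, 6 adjusted over the list alone (camera adjusted p = 1.1e-12, and 0.0024 with an estimated correlation). Tissue homing and adhesion (1 called), erythroid, CD8 and NK cell (lower), repair and growth factors, hypoxia and macrophage and monocyte were called by camera with adjusted p of 0.00015, 0.0037, 0.022, 0.043, 0.043 and 0.045. They were lost at 0.068, 0.22, 0.082, 0.22, 0.22 and 0.22 with an estimated correlation.

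By edgeR 8 genes were higher and 1 lower in spleen Tregs. DESeq2 called 607 higher and 291 lower, and the 16-library set alone, in which all spleen libraries lie, 14 and 8. The count was 18 without spleen Tconv replicate 2. Foxp3, Ctla4, Ikzf2 and Cep112 passed without any of the 6 libraries. Tnfsf8, Ccr3 and Lrrc32 were lost without some: 3 named genes ended without spleen Treg replicate 1 and 3 without replicate 2, 2 without spleen Tconv replicate 1, 1 without replicate 2 and 2 without replicate 3 (highest adjusted p 0.31). List calls ended without spleen Treg replicates 1 (3), 2 (4) and 3 (1) and Tconv replicates 1 (3), 2 (3) and 3 (2), with adjusted p of up to 0.24.

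In the NDLN, Foxp3 had 73.2 ± 32.5 CPM in Tregs and 0 counts in Tconvs, at least 1250-fold higher (adjusted p = 7e-06), and Ikzf2 was 31.6-fold higher (1490 ± 522 against 47.1 ± 17.1, adjusted p = 5.9e-05). From the TNF receptor and costimulation list, Tnfrsf1b, the TNF receptor 2 gene, was 425-fold higher in Tregs (84.9 ± 32.9 against 0.221 ± 0.333, adjusted p = 0.0012) and Tnfrsf9, the 4-1BB gene, 89.5-fold (adjusted p = 0.0071). Tnfrsf4, the OX40 gene, was 16.5-fold higher (1540 ± 147 against 93.4 ± 106, adjusted p = 0.0098) and Tnfrsf18 7.7-fold higher (932 ± 119 against 121 ± 24.4, adjusted p = 0.0098). Il2rb, the IL-2 receptor beta chain gene, was 28.8-fold higher (91.3 ± 29.4 against 3.14 ± 4.24, adjusted p = 0.036). H2-Aa was at 137 ± 47.3 CPM in Tregs and 2 counts in Tconvs (ratio 3550, 983 to 29300, adjusted p = 0.0051), while the B cell list was higher in the same libraries. Tnfsf8 was 6.69-fold lower in Tregs (37.6 ± 20.8 against 252 ± 60.8, adjusted p = 0.03). Emb, which encodes the membrane glycoprotein embigin, was 2.47-fold lower (212 ± 39.1 against 525 ± 128, adjusted p = 0.036).

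Also higher in NDLN Tregs were Cep112 (56.1 ± 24.5 CPM against 1 count, ratio 2850, 510 to 112000, adjusted p = 0.0051) and the chemokine receptor gene Ccr8 (44.2 ± 26.9 CPM against 3 counts, ratio 828, 283 to 4020, adjusted p = 0.021). The kinetochore gene Spc25 was higher too (121 ± 96.4 CPM against 1 count, ratio 6010, 1080 to 237000, adjusted p = 0.039). Against 0 counts in Tconvs, Swap70 was at least 681-fold, Bnip3, a mitophagy receptor gene, at least 451-fold, Nol10 at least 417-fold and Lrrc32 at least 236-fold higher (adjusted p = 0.041, 0.024, 0.021 and 0.02). Ctla4 was at 441 ± 107 and 142 CPM (log2 1.64, adjusted p = 0.26) and Il2ra at 311 ± 102 and 5.76 ± 9.97 (adjusted p = 0.41).

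The Treg identity list was higher in 21 of 21 members in the NDLN, 7 called and 16 adjusted over the list alone (camera adjusted p = 1.8e-23, and 5.1e-05 with an estimated correlation). The cell cycle list was higher in 22 of 23 (camera adjusted p = 7.2e-14, and 0.0095 with an estimated correlation). Here 0 were called by edgeR (14 at an unadjusted p under 0.05, 13 by DESeq2, 6 by limma-voom) and 14 passed adjusted over the list alone. TNF receptor and costimulation had 4 members called higher and 1 lower, and 7 and 2 adjusted over the list alone (camera adjusted p = 0.00071, and 0.021 with an estimated correlation). Lower in Tregs were the Tfh list, genes of T follicular helper cells, in 5 of 7 members, 3 adjusted over the list alone (camera adjusted p = 3.9e-06, and 0.0095 with an estimated correlation) and the naive and lymphoid homing list in 11 of 15 (7.8e-05, and 0.011). From the latter, Tcf7 was at 23.5 ± 5.74 against 271 ± 71.7 (adjusted p = 0.071). The B cell list was higher in 8 of 8 members (camera adjusted p = 2.1e-08, and 0.011 with an estimated correlation) and the dendritic cell list in 6 of 7, with H2-Aa called (7.8e-05, and 0.046). The tissue-repair Treg (2 called, 8 adjusted over the list alone, 2.7e-06, and 0.022) and suppressive effector lists (0.00071, and 0.046) were called and held, and tissue homing and adhesion (1 called, 0.00035) and glycolysis (0.0058) were lost with an estimated correlation (adjusted p = 0.072 and 0.19).

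Here 42 genes were higher and 3 lower in Tregs by edgeR. DESeq2 called 1201 and 443, limma-voom 217 and 45, and the 16-library set alone, in which all NDLN libraries lie, 15 and 3. The count was 26 without NDLN Treg replicate 2, 28 without NDLN Tconv replicate 1 and 87 without NDLN Tconv replicate 3. Of 18 named genes, 4, 6 and 5 were lost without NDLN Treg replicates 1, 2 and 3 and 11, 8 and 5 without NDLN Tconv replicates 1, 2 and 3 (highest adjusted p 0.17). Foxp3, H2-Aa, Ikzf2, Tnfrsf1b, Tnfrsf18 and Tnfrsf4 passed each time, and the glycolysis list was lost without NDLN Treg replicate 1 (adjusted p = 0.074).

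Across heart, spleen and NDLN, 4 genes were called higher in Tregs than in Tconvs each time and 0 lower. Foxp3 had log2 fold changes of 10.85, 11.31 and 13.67, Lrrc32 11.53, 11.91 and 11.38, Cep112 9.11, 12.65 and 11.12, and Ikzf2 4, 4.15 and 4.98, in that order of tissues. Fold changes against 0 to 3 counts are no bound. The 3 contrasts share no library but do share the estimate of spread, and Foxp3 marked the sorted cells. Independent lists, which these are not, would share 1e-05 genes higher and 4e-08 lower. DESeq2 shared 54 higher and 23 lower, limma-voom 10 and 2, and the count of shared genes was 2 without spleen Treg replicates 1 or 2, heart Treg replicate 2 or heart Tconv replicates 1 or 2.

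Heart Tregs were next set against Tregs of the lymphoid organs to ask what marks Tregs in the injured heart. Against the spleen, Dcn, the small proteoglycan decorin (ENSMUSG00000019929), was at 169 ± 154 CPM against 1 count (ratio 13200, 2360 to 520000, adjusted p = 0.022). Mgp, matrix Gla protein (ENSMUSG00000030218), was at 141 ± 136 CPM against 1 count (ratio 11000, 1970 to 435000, adjusted p = 0.036). Both stand in the fibroblast list, and Dcn was at 14.4, 323 and 168 CPM in the heart Treg libraries. Ctla2a, a cathepsin inhibitor gene, was 22.9-fold higher (439 ± 106 against 19.2 ± 5.94, adjusted p = 0.033) and Ifrd1, a transcriptional coregulator gene, 17.4-fold (744 ± 371 against 42.9 ± 8.42, adjusted p = 0.012). Ccr7 was 10.9-fold higher (792 ± 265 against 72.4 ± 38.7, adjusted p = 0.039) and Tnfsf8 8.55-fold (adjusted p = 0.022). Emb was 5.05-fold higher (1330 ± 338 against 263 ± 26.7, adjusted p = 0.00057). Arf4, a small GTPase gene of vesicle transport, was 4.57-fold higher and the ferritin heavy chain gene Fth1 3.79-fold (both adjusted p = 0.0037).

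Lower in heart than in spleen Tregs was H2-Aa, with 3 counts against 264 ± 95.5 CPM (ratio 6800, 2330 to 33000, adjusted p = 0.0037), in libraries where the B cell list was lower as well. Tlr1, a receptor of bacterial lipopeptides, had 4 counts against 54.9 ± 4.71 CPM (919-fold, adjusted p = 0.022). Id3, an inhibitor of E-protein transcription factors, was 6.49-fold lower (26 ± 13.2 against 169 ± 43.5, adjusted p = 0.028). Tmem60 was 8.12-fold lower, Ssna1 3.59-fold and mt-Nd6 4.02-fold (adjusted p = 0.028, 0.022 and 0.032). All mitochondrial genes took 0.956 (5-library set), 6.68 and 6.7% of counts in heart and 4.97 to 10.6% in spleen Tregs. Foxp3 did not pass (167 ± 71.1 against 88.9 ± 18.7, log2 0.91, SE 0.61, adjusted p = 0.55). Nor did Il2ra (adjusted p = 1), Cd4 (0.61), Cd3e (0.71) or Il1rl1 (102 ± 55.8 against 21.3 ± 10.8, 0.63). Ctla4 was at 1660 ± 500 against 547 ± 151 (log2 1.6, adjusted p = 0.32) and Areg at 323 ± 239 against 33.5 ± 18.4 (log2 3.27, adjusted p = 0.41). Sparc had 103 ± 56.3 CPM against 2 counts, a ratio of 3990 (1100 to 32900) that did not pass (adjusted p = 0.12).

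The fibroblast list was higher in heart than in spleen Tregs in 14 of 14 members tested, 2 called and 10 adjusted over the list alone (camera adjusted p = 2.2e-21, and 0.01 with an estimated correlation). Immediate early and TCR activation genes were higher in 19 of 21 members (camera adjusted p = 1.4e-06; adjusted p = 0.13 with an estimated correlation). By edgeR 0 were called, with 7 at an unadjusted p under 0.05, 6 called by DESeq2 and 3 by limma-voom, and 5 higher and 1 lower adjusted over the list alone. From that list, Junb, an AP-1 subunit gene, stood at 886 ± 360 against 109 ± 45.1 CPM (adjusted p = 0.054) and Nfkbia, an NF-kB inhibitor gene, at 2400 ± 388 against 844 ± 309 (adjusted p = 0.2). Glycolysis was higher in 14 of 16 (camera adjusted p = 5.2e-05; adjusted p = 0.097 with an estimated correlation). Its Eno1 and Ldha, an enolase and a lactate dehydrogenase gene, were at 831 ± 554 against 183 ± 86.7 (adjusted p = 0.16) and 2060 ± 330 against 761 ± 419 CPM (adjusted p = 0.35). The B cell list was lower in 8 of 8 members, 6 adjusted over the list alone (camera adjusted p = 1.2e-10, and 0.01 with an estimated correlation). The erythroid list was lower in 6 of 6 (1.1e-08; adjusted p = 0.068 with an estimated correlation). Ms4a1, the CD20 gene, stood at 0 counts against 52.8 ± 8.25 CPM and Hbb-bs, a beta-globin gene, at 9.23 ± 9.58 against 4440 ± 4540. Repair and growth factors (15 higher, 4 lower), tissue-repair Treg (14 of 19), suppressive effector (13 of 15) and Th2 (6 of 6) had camera adjusted p of 0.005, 0.0077, 0.0077 and 0.022. Heat shock (9 higher, 1 lower), hypoxia (10 of 12), tissue homing and adhesion (17 of 21) and dendritic cell (4 of 7 lower, with H2-Aa called) had 0.028, 0.035, 0.037 and 0.049. Their adjusted p with an estimated correlation were 0.13, 0.21, 0.13, 0.21, 0.14, 0.21, 0.27 and 0.28. Treg identity was not called (adjusted p = 0.21), nor TNF receptor and costimulation (0.099) or Th1 (0.051).

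Against spleen Tregs 14 genes were higher and 8 lower by edgeR. DESeq2 called 465 and 887, limma-voom 107 and 123, and the 16-library set alone 6 and 9. The count was 8, 5 and 5 without spleen Treg replicates 1, 2 and 3, 14 without heart Treg replicate 3, and 11 higher with 18 lower without heart Treg replicate 1, which is in the 5-library set. Of the 12 called genes that the naming rule took from this contrast, H2-Aa passed each time, and 10, 11 and 11 were lost without spleen Treg replicates 1, 2 and 3 and 7, 6 and 8 without heart Treg replicates 1, 2 and 3 (highest adjusted p 0.28). Of 13 list calls, 0, 3 and 8 ended without spleen Treg replicates 1, 2 and 3 and 5, 6 and 6 without heart Treg replicates 1, 2 and 3 (highest 0.2). Immediate early and TCR activation, glycolysis, fibroblast, B cell and erythroid held each time.

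**Figure D4:**
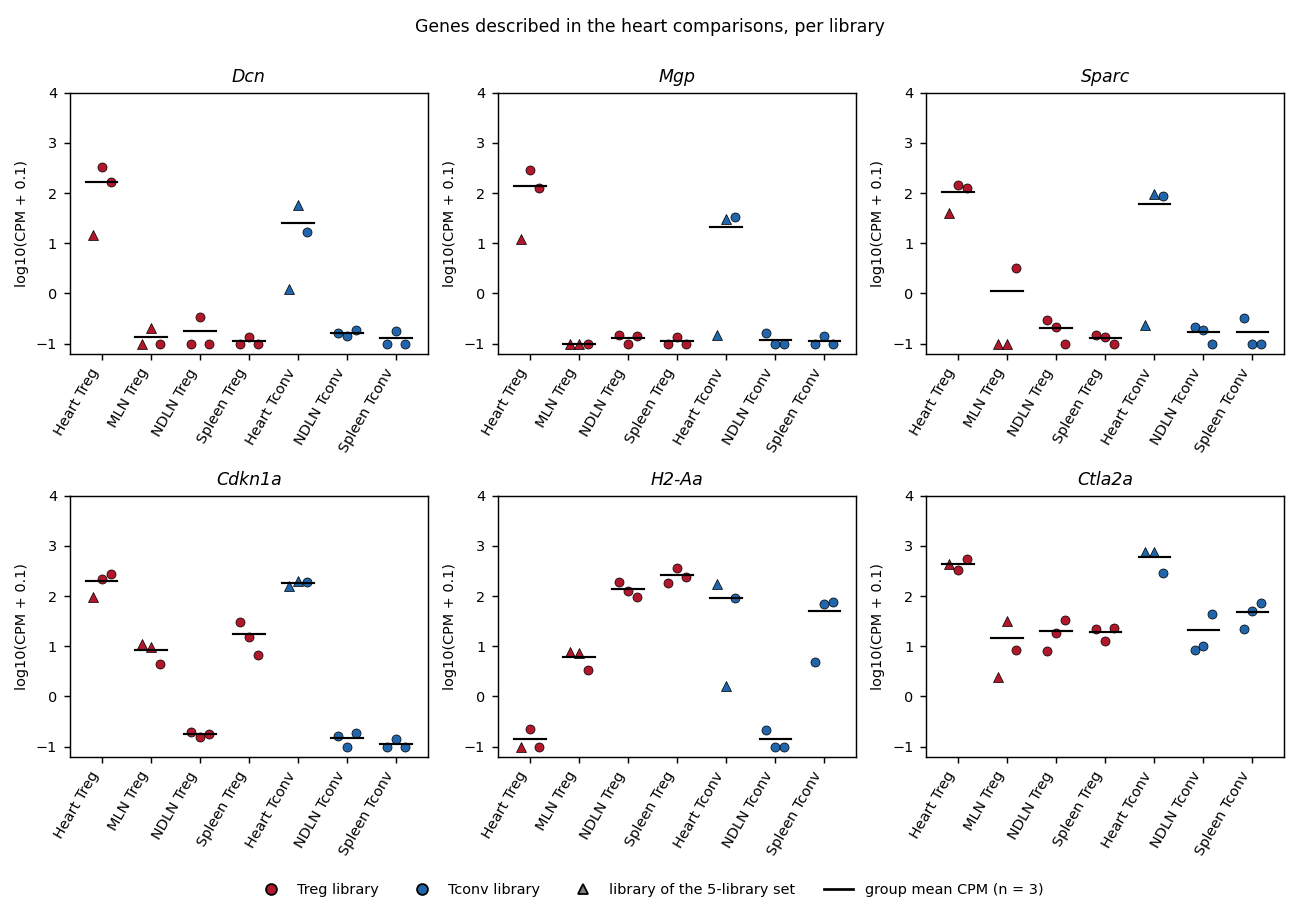
Levels of Dcn, Mgp, Sparc, Cdkn1a, H2-Aa and Ctla2a in each library, as log10(CPM + 0.1) on the y axis, by group on the x axis; the lines are group means (n = 3) and triangles mark the 5-library set. Dcn lies at 14.4, 323 and 168 CPM in the heart Tregs, and H2-Aa at a mean of 264 CPM in spleen Tregs and 0.0395 in heart Tregs.

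Against NDLN Tregs, Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067), was higher in heart Tregs at 195 ± 88.1 against 0.0777 ± 0.0187 CPM (log2 fold change 11.18, SE 1.06, adjusted p = 1.9e-05). Atf3, a stress-induced transcription factor gene, had 58.3 ± 29.3 CPM against 1 count (ratio 3610, 647 to 143000, adjusted p = 0.025). Got1, an aspartate aminotransferase gene, was 56.9-fold and Dusp10, a MAP kinase phosphatase gene, 29.4-fold higher (both adjusted p = 0.013). Emb (6.26-fold, adjusted p = 4.6e-05), Arf4 (5.49-fold, 0.00047), Ctla2a (22.2-fold, 0.019) and Fth1 (3.06-fold, 0.0096) were higher here too, as were Mgp (ratio 4600, 1270 to 37900, 0.026) and Dcn (2170-fold, 0.023). From the immediate early and TCR activation list, Junb was 14.2-fold higher (886 ± 360 against 62.4 ± 31.5, adjusted p = 0.0083), Tnfaip3, a brake on NF-kB signalling, 9.26-fold (665 ± 195 against 71.8 ± 68.6, adjusted p = 0.016) and Nfkbia 4.08-fold (adjusted p = 0.026).

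Id2, a transcriptional inhibitor of effector T cells, was 5.32-fold higher in heart than in NDLN Tregs (adjusted p = 0.016). Selplg, the P-selectin ligand gene, was 5.44-fold higher (580 ± 211 against 107 ± 28.8, adjusted p = 0.018) and Eno1 6.71-fold (adjusted p = 0.034). Lower were H2-Aa (3 counts against 137 ± 47.3 CPM, ratio 3350, 1150 to 16200, adjusted p = 0.0038), Tlr1 (1380-fold, 0.0096) and Id3 (8.92-fold, 26 ± 13.2 against 232 ± 74.9, 0.0083). So were the nucleoporin gene Nup37 (ratio 2520, 863 to 12200, 0.029), Alg14 (208-fold, 0.036) and Trmt11 (8.63-fold, 0.034). Foxp3 was at 167 ± 71.1 against 73.2 ± 32.5 CPM (log2 1.19, adjusted p = 0.33), and Ctla4 at 1660 ± 500 against 441 ± 107 (1.91, 0.094). Ccr7 was at 792 ± 265 against 118 ± 85.9 (2.75, 0.067), Areg at 323 ± 239 against 29.7 ± 31.7 (3.44, 0.23) and Sparc at 103 ± 56.3 CPM against 6 counts (9.92, 0.094).

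The fibroblast list was again higher in 14 of 14 members, 2 called and 10 adjusted over the list alone (camera adjusted p = 2.5e-17, and 0.036 with an estimated correlation). The B cell list was lower in 8 of 8, 5 adjusted over the list alone (3e-07, and 0.046). Immediate early and TCR activation had 3 members called, and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 8e-07; adjusted p = 0.058 with an estimated correlation). The tissue-repair Treg list was higher in 17 of 19 members (camera adjusted p = 3.2e-05), tissue homing and adhesion in 19 of 21 (3.6e-05), glycolysis in 15 of 16 (3.2e-05) and hypoxia in 10 of 12 (0.00045). Each of the first 3 had 1 member called and hypoxia 0 (3 at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma-voom), and each an adjusted p of 0.05 with an estimated correlation. The suppressive effector (14 of 15, 0.0011), Th1 (9 of 10, 0.0027), Th2 (6 of 6, 0.001) and repair and growth factor lists (0.00026) were lost as well with an estimated correlation (adjusted p = 0.056, 0.056, 0.058 and 0.05).

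By edgeR 48 genes were higher and 32 lower than in NDLN Tregs. Median-of-ratios scaling gave 49 and 20, DESeq2 863 and 971, limma-voom 207 and 170, and the 16-library set alone 21 and 14. The count was 12 without NDLN Treg replicate 2, 23 without replicate 3, 48 without heart Treg replicate 3, and 28 higher with 37 lower without heart Treg replicate 1. Of 19 named genes, 5, 13 and 15 were lost without NDLN Treg replicates 1, 2 and 3 and 6, 6 and 7 without heart Treg replicates 1, 2 and 3 (highest adjusted p 0.18), Junb, Tnfaip3 and Id2 among them. H2-Aa, Tlr1, Id3 and Cdkn1a passed each time, and no list call ended.

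Against MLN Tregs, Emb was 6.57-fold higher in heart Tregs (1330 ± 338 against 202 ± 46, log2 2.71, SE 0.28, adjusted p = 6.2e-05). Mgp, with 0 counts in MLN Tregs, was at least 3210-fold higher (adjusted p = 0.047) and Dcn, with 2 counts, stood at a ratio of 5760 (1590 to 47500, adjusted p = 0.048). Ctla2a was 30.7-fold, Cdkn1a 23.4-fold (195 ± 88.1 against 8.36 ± 3.51), Arf4 3.11-fold and Fth1 2.82-fold higher, and Tlr1 851-fold lower (each adjusted p = 0.047). Foxp3 (167 ± 71.1 against 91.2 ± 39.4, adjusted p = 0.68) and Areg (323 ± 239 against 98.3 ± 80.1, 0.62) did not pass. Neither did Il1rl1 (102 ± 55.8 against 10.4 ± 9.75, 0.51), Ctla4 (1660 ± 500 against 575 ± 72.6, 0.46) and Sparc (103 ± 56.3 against 1.01 ± 1.76, 0.49).

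The fibroblast list was higher than in MLN Tregs in 14 of 14 members, 2 called and 9 adjusted over the list alone (camera adjusted p = 4.3e-26, and 0.0063 with an estimated correlation). The tissue-repair Treg list was higher in 18 of 19 (camera adjusted p = 0.00013), tissue homing and adhesion in 15 of 21 (0.0038) and immediate early and TCR activation in 16 of 21 (0.0035). Suppressive effector was higher in 12 of 15 (0.0062), Th2 in 6 of 6 (0.0062), and Th1 in 9 of 10 (0.0066). Repair and growth factors were higher in 14 of 20 (0.009), hypoxia in 10 of 12 (0.023) and endothelial in 3 of 3 (0.031), and the erythroid list was lower in 6 of 6 (6.5e-06). With an estimated correlation their adjusted p were 0.15 to 0.27. By edgeR 7 genes were higher and 3 lower. DESeq2 called 318 and 794, limma-voom 72 and 94, median-of-ratios scaling 1 and 1, and the 16-library set alone, with 1 MLN library, 0 (1436 genes had an unadjusted p under 0.05 with all libraries). MLN Treg replicates 1 and 2 and heart Treg replicate 1 are in the 5-library set. The count was 2, 4 and 1 without MLN Treg replicates 1, 2 and 3, 4 and 2 without heart Treg replicates 2 and 3, and 11 higher with 17 lower without heart Treg replicate 1. Of 7 named genes, Emb passed each time, and 6, 5 and 6 were lost without MLN Treg replicates 1, 2 and 3 and 1, 5 and 6 without heart Treg replicates 1, 2 and 3 (highest adjusted p 0.31). Of 11 list calls, 4, 1 and 4 ended without MLN Treg replicates 1, 2 and 3 and 2, 4 and 1 without heart Treg replicates 1, 2 and 3 (highest 0.3). Tissue-repair Treg, immediate early and TCR activation, fibroblast and erythroid held each time.

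Against all 3 lymphoid Treg groups, 6 genes were higher in heart Tregs and 3 lower. Emb had log2 fold changes of 2.34, 2.65 and 2.71 against spleen, NDLN and MLN, Arf4 2.19, 2.46 and 1.64, Fth1 1.92, 1.62 and 1.5, and Ctla2a 4.52, 4.48 and 4.94. Mgp and Dcn had 11.08 or more in each, against groups with 0 to 4 counts. Tlr1 was lower, with the predicted genes D330023K18Rik and Gm19261, which stand outside the naming rule and were added after their values were seen. The contrasts share the heart Treg libraries, and independent lists would share 2.1e-05 higher and 3.4e-06 lower. In 20 simulations of unchanged groups edgeR called 0 genes in any contrast, which gives no measure of sharing. Of the 1000 genes of smallest p in each contrast, 324 moved the same way in all 3, against a mean of 121 and at most 143 in the simulations. This may come from the shared libraries or the library set. DESeq2 gave 95 higher and 496 lower, limma-voom 57 and 21 and median-of-ratios scaling 1 and 1. Every left-out library changed the count by over 1.5 times: 21 without heart Treg replicate 1, 5 without NDLN Treg replicate 1, 4 without MLN Treg replicate 2 or heart Treg replicate 2, 1 without MLN Treg replicate 3 and 2 without each of the others. Within the 16-library set, with 1 MLN library, it was 0 by edgeR, and with the set as a covariate 8, which include 6 of the 9.

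MLN and NDLN Tregs were compared to see whether draining of the heart shows in lymph node Tregs. Cdkn1a was the single gene called, 99.5-fold higher in MLN Tregs (8.36 ± 3.51 against 0.0777 ± 0.0187, log2 6.64, SE 0.91, adjusted p = 0.0064); it lies below the CPM minimum of the naming rule and was added after its values were seen. Foxp3 was at 91.2 ± 39.4 and 73.2 ± 32.5 CPM (log2 0.32, adjusted p = 0.98). Junb stood at 750 ± 509 against 62.4 ± 31.5 CPM (adjusted p = 0.11) and Hbb-bs at 2970 ± 4900 against 0.459 (adjusted p = 0.25). The erythroid list was higher in 6 of 6 members (camera adjusted p = 2.2e-06), and glycolysis (0.015) and immediate early and TCR activation (0.029) were higher too. The B cell (6 of 8 lower, 0.001) and dendritic cell lists (6 of 7 lower, 0.016) were lower. Their adjusted p with an estimated correlation were 0.35, 0.47, 0.7, 0.35 and 0.47. DESeq2 called 660 genes higher and 281 lower and limma-voom 110 and 61. EdgeR called 0 without NDLN Treg replicates 2 or 3 and in the 16-library set alone, with 1 MLN library, and 5 without NDLN Treg replicate 1 or MLN Treg replicate 3. Immediate early and TCR activation ended without NDLN Treg replicates 2 or 3 and MLN Treg replicates 2 or 3, glycolysis without NDLN Treg replicate 2 and MLN Treg replicate 1, and dendritic cell without these and MLN Treg replicate 3 (highest adjusted p 0.33).

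Tconvs of the heart were set against those of the lymphoid organs to ask which tissue differences are seen without Foxp3. Against the spleen, Cdkn1a had 183 ± 20.1 CPM in heart Tconvs and 1 count (log2 fold change 13.13, SE 1.17, ratio 12100, 2160 to 477000, adjusted p = 6.1e-06). Atf3 had 161 ± 82.4 CPM against 1 count (ratio 10600, 1900 to 418000, adjusted p = 0.021). Mxd1, a MYC antagonist gene, was 102-fold higher (adjusted p = 0.03) and Tnfrsf1b 40.3-fold (113 ± 35 against 2.8 ± 2.45, adjusted p = 0.017). Junb was 7.45-fold higher (1420 ± 593 against 191 ± 60.9, adjusted p = 0.034) and Ctla4 6.8-fold (166 ± 40.7 against 24.4 ± 15.7, adjusted p = 0.021). The chaperone genes Hspa8 (5.05-fold, 2680 ± 689 against 530 ± 145, adjusted p = 0.017) and Dnaja1 (2.41-fold, 0.03) were higher, as was Nfkbia (4.73-fold, 0.021). Hif1a, the oxygen-sensing transcription factor gene (3.86-fold, 509 ± 89 against 132 ± 23.7, 0.029), was higher as well. Pmepa1, a gene induced by TGF-beta, was at least 1030-fold (adjusted p = 0.033) and Dcn at a ratio of 863 (239 to 7130, 0.044). The mitochondrial genes mt-Nd6 (6.05-fold, 0.0052) and mt-Cytb (5.27-fold, 3530 ± 1700 against 18600 ± 5260, 0.028), the complex I assembly gene Ndufaf3 (6.18-fold, 0.031), Rpf2 (5.23-fold, 0.024), Tmem261 (4.95-fold, 0.046) and Mgst2 (4.88-fold, 0.012) were lower. Mitochondrial genes as a whole took 1.84% of counts in heart Tconvs and 7.99% in spleen Tconvs, and 2 of the 3 heart Tconv libraries are in the 5-library set.

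Lists higher in heart than in spleen Tconvs included immediate early and TCR activation (18 of 21 members, 2 called, 12 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.5e-05) and heat shock (9 of 11, 2 called, 7 higher and 1 lower adjusted over the list alone; 0.0016). So were glycolysis (16 of 16; 0.0003), Treg identity (1 called, 6 adjusted over the list alone; 0.00042), tissue homing and adhesion (0.0018), repair and growth factors (0.0046), hypoxia (1 called; 0.011) and Th1 (0.024), and with them fibroblast (13 of 14, 1 called, 9 adjusted over the list alone; 8e-06). The erythroid list was lower in 5 of 6 (2.6e-05). These were lost with an estimated correlation, at an adjusted p of 0.076 for heat shock and Treg identity and 0.13 for the others. Tissue-repair Treg (18 of 19, camera adjusted p = 1.4e-06) and suppressive effector (15 of 15, 1 called, 1.2e-05) held with an estimated correlation (both adjusted p = 0.048). Sparc was at 60.8 ± 52.6 CPM against 5 counts (adjusted p = 0.092), Areg at 63.5 ± 37.1 against 4.28 (0.15) and Ccr7 at 854 ± 258 against 393 ± 155 (0.44).

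By edgeR 46 genes were higher and 25 lower than in spleen Tconvs. DESeq2 called 894 and 576, the fit with the library set as a covariate 10 and 2, and the 16-library set, with 1 heart Tconv library, 1 and 0. The count was 12 and 3 without spleen Tconv replicates 1 and 3, 16 and 8 without heart Tconv replicates 1 and 2, and 187 without heart Tconv replicate 3 (61 higher, 126 lower). The stricter filter gave 62 higher and 63 lower. Of 18 named genes, 16, 8 and 16 were lost without spleen Tconv replicates 1, 2 and 3 and 13, 16 and 1 without heart Tconv replicates 1, 2 and 3 (highest adjusted p 0.28). Cdkn1a passed each time, and Th1 ended without spleen Tconv replicate 3 (0.11) or heart Tconv replicate 3 (0.12).

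Against NDLN Tconvs, heart Tconvs had more Tnfsf11, the RANK ligand gene, at 229 ± 127 CPM against 0 counts (at least 3970-fold, adjusted p = 0.0071). Also higher were Atf3 (at least 2810-fold, 0.0071), Cdkn1a (ratio 4810, 1330 to 39800, 1.4e-05) and Ccr8 (139 ± 52.7 CPM against 3 counts, ratio 2410, 826 to 11700, 0.0043). Tnfrsf1b was 567-fold higher (113 ± 35 against 0.221, log2 9.15, adjusted p = 0.00079) and Il2rb 58.8-fold (186 ± 105 against 3.14 ± 4.24, adjusted p = 0.0064). From the Th1 list, Nkg7, a cytotoxic granule gene, was 25.4-fold higher (1180 ± 441 against 46.6 ± 19.1, adjusted p = 0.01), and the chemokine receptor gene Cxcr3 18.5-fold (197 ± 41.5 against 10.7 ± 8.97, 0.03). The CD8 and NK cell list summed to 472 ± 86.6 against 108 ± 37.1 CPM, with those cells as a source not tested. Cd44, an adhesion receptor of antigen-experienced T cells, was 4.67-fold higher (309 ± 48.7 against 66.2 ± 28.8, 0.033) and Lgals3, the galectin-3 gene, 31.5-fold (0.02). From the glycolysis list, Eno1 was 12.5-fold higher (950 ± 361 against 76.2 ± 41, adjusted p = 0.0043), Gpi1 12.4-fold (0.018), Ldha 3.92-fold (0.025) and Hk2 at least 400-fold (0.018). H2-Aa was at 89.8 ± 87.9 CPM, uneven between libraries, against 2 counts (ratio 2290, 633 to 18900, 0.0029).

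Further genes higher in heart than in NDLN Tconvs were Dnajc4, Fech, Irs2 and Racgap1, at least 723-, 684-, 683- and 629-fold (adjusted p = 0.02, 0.03, 0.019 and 0.044). The decoy IL-1 receptor gene Il1r2 (ratio 4690, 842 to 185000, 0.0069) and Il1rl1 (at least 117-fold, 0.044) were raised. The fibroblast genes Dcn (ratio 459, 157 to 2230, 0.023) and Mgp (ratio 1140, 204 to 44900, 0.023) were higher too. Lower were Sh2d1a, which encodes the adaptor SAP (140 ± 53.6 against 489 ± 202, 3.48-fold, adjusted p = 0.02), the mitochondrial genes mt-Nd3 (15.6-fold, 0.01) and mt-Atp6 (8.66-fold), and Ppil3 (9.57-fold), Sdhaf4 (9.14-fold), Ndufaf3 (8.16-fold) and BE692007 (8.14-fold, 0.0071). Mitochondrial genes took 1.84% of counts in heart Tconvs and 14.3% in NDLN Tconvs, and ribosomal protein genes 8.28% and 21.4%. Sparc was at 60.8 ± 52.6 CPM against 4 counts (adjusted p = 0.051). Cd3e, a T cell receptor complex gene, was 3.04-fold higher (308 ± 109 against 101 ± 44.4, 0.039), and was lost without any 1 of the 6 libraries (highest 0.15).

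Of the lists, glycolysis was higher in heart than in NDLN Tconvs in 16 of 16 members, 4 called and 10 adjusted over the list alone (camera adjusted p = 1.9e-05). Tissue homing and adhesion was higher in 18 of 21, 5 called and 13 adjusted over the list alone (3.3e-05), and tissue-repair Treg in 18 of 19, 4 called and 12 adjusted over the list alone (3.3e-05). Th1 was higher in 10 of 10, 3 called and 6 adjusted over the list alone (5.7e-05). Treg identity (5 called, 0.0012), hypoxia (2 called, 0.0011) and Tfh (6 of 7 lower, 1 called, 0.003) followed, and with an estimated correlation all of these had an adjusted p of 0.065. Immediate early and TCR activation (6 called, 0.0012), fibroblast (12 of 14, 2 called, 0.0012), and dendritic cell (7 of 7, 2 called, 0.0024) were lost at 0.21, 0.22 and 0.14 with an estimated correlation. Suppressive effector (14 of 15, 0.019), TNF receptor and costimulation (4 called, 0.023), repair and growth factors (1 called, 0.03) and Th17 (7 of 9, 0.03) were lost at 0.16, 0.11, 0.21 and 0.21. In the 16-library set alone the Th17 list was lower in heart Tconvs, without passing (adjusted p = 0.9).

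Here edgeR called 231 genes higher and 201 lower. DESeq2 called 1919 and 787, limma-voom 867 and 415, the fit with the library set as a covariate 67 and 13 and the 16-library set alone, with 1 heart Tconv library, 25 and 9. The count was 287 without NDLN Tconv replicate 3, 122 without heart Tconv replicate 1 (104 higher, 18 lower) and 96 without heart Tconv replicate 2 (79 higher, 17 lower). Of 51 named genes, 23, 25 and 32 were lost without NDLN Tconv replicates 1, 2 and 3 and 24, 34 and 8 without heart Tconv replicates 1, 2 and 3 (highest adjusted p 0.24). Suppressive effector and TNF receptor and costimulation ended without NDLN Tconv replicate 3 (0.13 and 0.058) or heart Tconv replicate 3 (0.11 and 0.1), and Th17 without heart Tconv replicate 2 (0.18).

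Some genes were called in the same direction in heart Tregs and heart Tconvs. Against the spleen, 8 genes were called higher and 1 lower in both cell types. The contrasts share the estimate of spread but no library, and independent lists would share 0.043 and 0.013. Against the NDLN, 39 were higher and 13 lower, where independent lists would share 0.74 and 0.43. Heart libraries of both cell types include some of the 5-library set, and spleen and NDLN libraries none. With the library set as a covariate, 3 genes higher and 1 lower were shared against the spleen (0.008 and 0.0012 for independent lists) and 19 and 3 against the NDLN (0.2 and 0.027). Between heart Tregs against spleen and against NDLN Tregs, which share the heart Treg libraries, 11 genes higher and 8 lower were shared, with 0.045 and 0.017 for independent lists. Of the 1000 genes of smallest p in each, 549 moved the same way, against a mean of 276 and at most 294 in the simulations. This may come from the shared libraries or the library set.

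Whether the difference between Tregs and Tconvs departs between tissues was tested by interaction. Against the spleen, H2-Aa and Cdkn1a were called, with log2 differences of -13.34 (SE 2.03, adjusted p = 0.015) and -9.64 (SE 1.23, adjusted p = 0.0022). Cdkn1a was at 195 ± 88.1 and 183 ± 20.1 CPM in heart Tregs and Tconvs, and at 17.4 ± 11.8 and 0.0131 in spleen Tregs and Tconvs. Against the NDLN, H2-Aa (-22.52, SE 2.46, adjusted p = 0.0002) and Tnfrsf1b (-8.01, SE 1.32, adjusted p = 0.045) were called. Tnfrsf1b was at 187 ± 65.1 and 113 ± 35 CPM in heart Tregs and Tconvs and at 84.9 ± 32.9 and 0.221 in the NDLN. DESeq2 called 158 genes higher and 686 lower for the spleen and 264 and 1111 for the NDLN. Without heart Treg replicate 1 the spleen count was 10, and 1 without spleen Tconv replicate 3. For the NDLN it was 40, 8 and 4 without NDLN Tconv replicates 3, 2 and 1, 4 without heart Treg replicate 1, and 1 without NDLN Treg replicates 2 or 3 or heart Tconv replicates 1 or 3. H2-Aa was lost for the spleen without heart Treg replicate 3 (adjusted p = 0.075), spleen Tconv replicate 2 (0.051) or 3 (0.085). Tnfrsf1b was lost for the NDLN without each of 9 libraries, all but NDLN Treg replicate 1 and NDLN Tconv replicates 2 and 3 (highest 0.16).

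**Figure D5:**
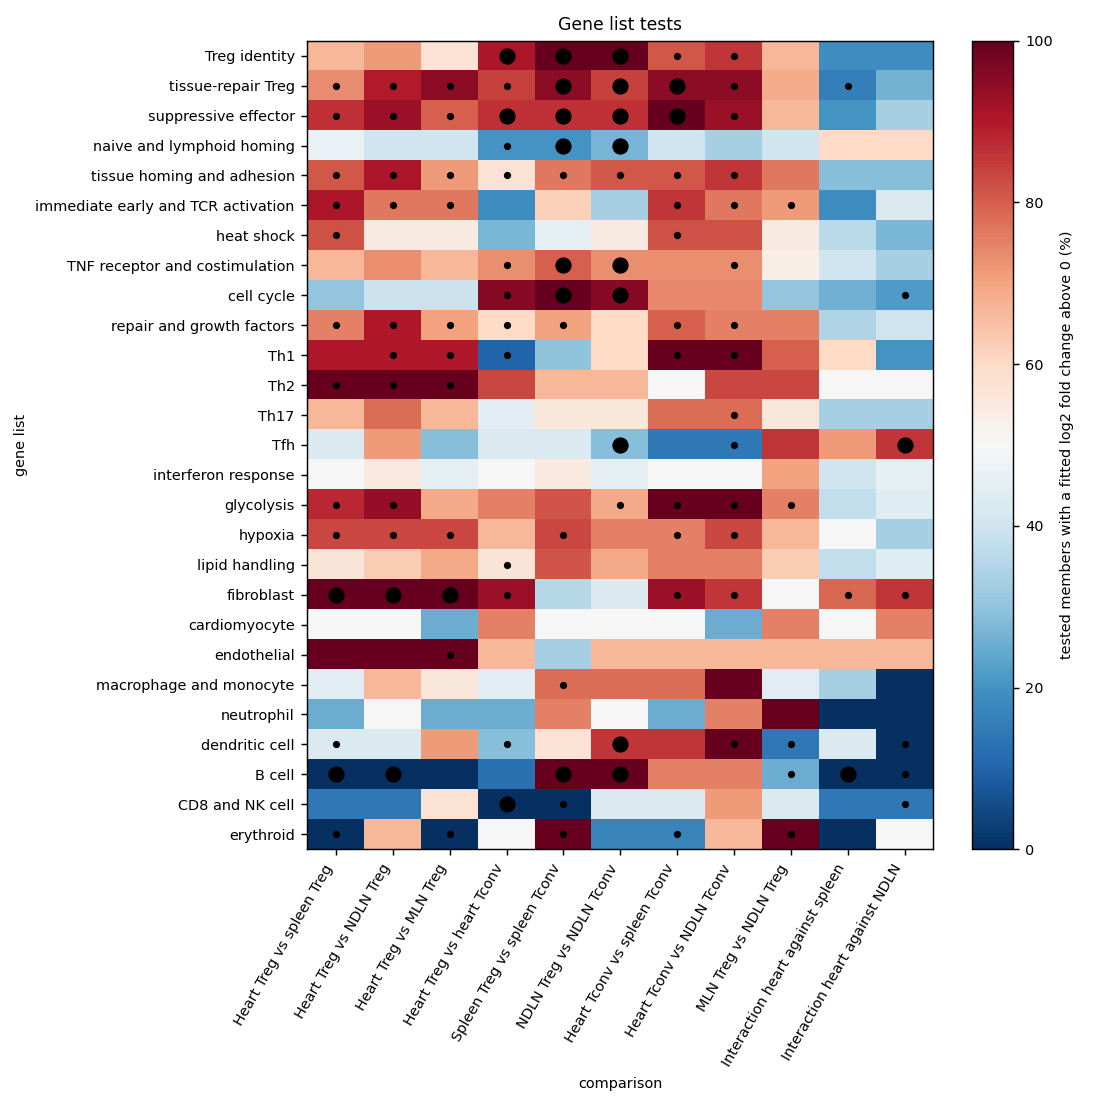
Heat map of the 27 gene lists (rows) in 11 contrasts (columns); colour gives the percentage of tested members with a log2 fold change above 0. Small dots mark camera calls at an adjusted p under 0.05 and large dots those that also pass with an estimated correlation. The fibroblast list for heart Tregs against each lymphoid Treg group is at 14 of 14 members, and Treg identity is called in Tregs against Tconvs of heart, spleen and NDLN.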

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

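All tests that weigh explanations in this part, and the divisions of the libraries that go with them, were chosen after the results they bear on had been seen; the interactions themselves were planned.

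The difference between Tregs and Tconvs departed between heart and spleen in 2 genes by a test of the interaction, Cdkn1a (log2 -9.64) and H2-Aa (-13.34). Between heart and NDLN it departed in 2 as well, Tnfrsf1b (-8.01) and H2-Aa (-22.52). Fold changes that rest on 0 to 3 counts in a group are no bound. Among the lists, the interaction with the spleen was called by camera for tissue-repair Treg (adjusted p = 0.028), fibroblast (adjusted p = 2.2e-06) and B cell (adjusted p = 9.4e-10). The Treg minus Tconv difference was lower in heart than in spleen in 16 of 19, 3 of 14 and 8 of 8 of their members, where the median log2 difference over all genes was -0.31 (-0.37 for the NDLN). With an estimated correlation these had an adjusted p of 0.45, 0.45 and 0.025. The interaction with the NDLN was called for cell cycle (difference lower in heart in 18 of 23, adjusted p = 0.042), Tfh (6 of 7 higher, 1.6e-05), fibroblast (12 of 14 higher, 2.2e-07), dendritic cell (7 of 7 lower, with H2-Aa called, 1e-05), B cell (8 of 8 lower, 4.7e-07) and CD8 and NK cell (6 of 7 lower, 0.012). With an estimated correlation their adjusted p were 0.52, 0.035, 0.11, 0.063, 0.05 and 0.088. The tissue-repair Treg list ended without spleen Treg replicate 1 (adjusted p = 0.077), spleen Tconv replicate 3 (0.16) or heart Tconv replicate 3 (0.062). The cell cycle list ended without NDLN Treg replicate 2 (0.16), heart Treg replicate 1 (0.27), NDLN Tconv replicates 1 (0.14) or 3 (0.2), or heart Tconv replicates 1 (0.059) or 3 (0.064).

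Of 100 divisions of the same libraries, 8 gave as many genes as the interaction with the spleen (2 genes; highest other 459) and 11 as many as that with the NDLN (2; highest other 1213), so chance cannot be excluded for either count. The largest of these exchange the labels of heart Tconvs with those of spleen or NDLN Tconvs, and so add up the tissue differences of Tregs and Tconvs, which is a structure of the samples. For the heart Treg signature (9 genes, highest other 71), 2 of 100 divisions gave as many. As 97 of them gave 0, this says only that a count above 0 is rare. It cannot exclude chance, nor show that the genes are shared beyond the common libraries. The division with 71 genes, that by library set, gives the heart label to MLN Treg replicates 1 and 2 and heart Treg replicate 1. With the set as a covariate the signature held 8 genes, which include 6 of the 9. For the Treg signature shared by 3 tissues (4 genes, highest other 0), only the real division of the 100 gave as many. The other 99 gave 0, which again says only that a count above 0 is rare. As Foxp3, 1 of the 4 genes, marked the sorted cells, this cannot exclude chance for the other genes.

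With 3 libraries against 3 there are 10 divisions, too few for a share under 0.05. The real one alone gave as many genes, which is 1 division, in heart against spleen Tregs (22 genes; highest other 1), heart against NDLN Tregs (80; 0), spleen Tregs against Tconvs (9; 1), NDLN Tregs against Tconvs (45; 8), heart against spleen Tconvs (71; 1), heart against NDLN Tconvs (432; 1) and MLN against NDLN Tregs (1; 0). In heart against MLN Tregs (10 genes; highest other 116) and heart Tregs against heart Tconvs (10; 99) it was 2 divisions, and the other is the division by library set; with the set as a covariate these comparisons gave 13 and 9 genes.

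The first pattern weighed is the division of the libraries into 5 and 16 that 26 genes followed. Tissue or cell type as its source is argued against by 3 of the 7 groups having libraries in both sets. Sequencing depth is argued against as well: the least of the missing genes would have had 400 counts in the shallowest of the 5 libraries, where the highest count seen was 4. A difference in alignment or annotation between the sets remains a candidate explanation, since 10 of the 26 genes lay within 100000 bases of another of the 26, where 10000 random draws of as many genes gave a median of 0 and 2 at the 95th percentile. No biological explanation beyond tissue and cell type was tested, and the labels name no batch.

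The pattern weighed next is the fibroblast genes, with Sparc, in heart T cell libraries. Fibroblasts or their RNA in the heart Treg libraries remain a candidate source: over the 6 heart libraries, centred within each group, the 14 members tested rose and fell together with a mean pairwise correlation of 0.43, against a median of -0.0035 and 0.13 at the 95th percentile of random lists matched on mean expression there. That 14 of 14 were higher in heart Tregs is the pattern itself and does not bear on its source, and the library set, which divides both heart groups, was not removed. Dcn, 1 of its members, reached 323 CPM, and bead enrichment followed by a sort of Foxp3-GFP cells is meant to remove whole fibroblasts. Whether Sparc may come from the heart Tregs themselves cannot be told apart from this: its log2 fold change of 0.76 between heart Tregs and heart Tconvs lay within the range of the list members, -0.44 to 3.21, and a tissue difference in the T cells stays open and untested.

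The last pattern weighed is H2-Aa, high in spleen and NDLN Tregs, at 177, 1.48 and 90.6 CPM in the heart Tconv libraries and at about 0 in heart Tregs. B cells were weighed as the source in heart Tconvs. Of 3 heart Tconv libraries, 2 had at least 10 CPM of H2-Aa. In these the B cell list summed to at most 0.22 of it, below 1.4 to 3.2 in the 6 spleen and NDLN Treg libraries. This argues against B cells there only if the list marks B cells in those Treg libraries, which was not tested. For the spleen and NDLN Tregs B cells or their RNA remain an untested candidate source. That 8 of 8 B cell genes were higher there than in heart Tregs and same-tissue Tconvs was known before and is no test. Random lists of genes highest in a lymphoid Treg group gave a median of 3, 5 at the 95th percentile and at most 8. In spleen Tregs Cd79a was at 148 ± 92.7 CPM and Ms4a1 at 52.8 ± 8.25. Whether dendritic cells may bring it into heart Tconvs cannot be told from these counts. Of 6 members, 4 were higher there than in heart Tregs and other Tconvs, against 4 at the 95th percentile of random lists. Dendritic cells in lymphoid Tregs were not tested. Bead enrichment and the T cell sort are meant to remove both cell types, and T cells of different tissues that differ in H2-Aa stay open and untested.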

How the results depend on the processing

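The fits that use the library set were chosen after the data had been seen, and all others were planned. Values follow the order heart against spleen, NDLN and MLN Tregs, Tregs against Tconvs in heart, spleen and NDLN, heart against spleen and NDLN Tconvs, MLN against NDLN Tregs, the interactions with spleen and NDLN, the heart Treg signature and the shared Treg signature. The counts by edgeR were 22, 80, 10, 10, 9, 45, 71, 432, 1, 2, 2, 9 and 4 genes.

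With DESeq2 the counts were 1352, 1834, 1112, 981, 898, 1644, 1470, 2706, 941, 844, 1375, 591 and 77, and with limma-voom 230, 377, 166, 165, 258, 262, 1170, 1282, 171, 45, 53, 78 and 12. Without a filter on low counts they were 189, 351, 118, 105, 158, 339, 354, 785, 193, 60, 178, 66 and 37. With only the groups compared in the fit, so fewer samples and fewer genes tested (9874 to 13517), they were 6, 14, 0, 1, 1, 0, 20, 28, 0, 1 and 2 for the contrasts. Beside the 0 by edgeR, the unadjusted p was under 0.05 in 1436, 1737 and 1449 genes with all groups in the fit. Within the 16-library set they were 15, 35, 0, 7, 22, 18, 1, 34, 0, 0, 1, 0 and 2, and within the 5-library set 1 for heart against MLN Tregs and 17 for heart Tregs against heart Tconvs. Arms of 1 library (MLN Tregs and heart Tconvs in the 16, heart Tregs in the 5) are assumed to vary like the other groups. With the set as a covariate 4 counts moved by over 1.5 times: heart against spleen and NDLN Tconvs, to 12 and 80, MLN against NDLN Tregs, to 3, and the interaction with the NDLN, to 1. Median-of-ratios scaling moved 3: heart against MLN Tregs, to 2, the interaction with the NDLN, to 1, and the heart Treg signature, to 2. The stricter filter moved heart against spleen Tconvs to 125. Apart from the changes of tool, of genes tested and of samples, the cause was not tested.

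With a replicate block, 7 counts moved by over 1.5 times: heart against NDLN Tregs to 146 (73 higher, 73 lower), heart against MLN Tregs to 4, heart against spleen Tconvs to 287 (91 higher, 196 lower), MLN against NDLN Tregs to 4, both interactions to 1 and the heart Treg signature to 4 (3 higher, 1 lower). The labels do not say whether a replicate number marks a shared source, and the data leave it open: in 0 of 21 pairs of groups did all same-numbered libraries deviate together with a correlation over 0.1, while 15 of 21 libraries correlated best with libraries of their own number, a hint from the data and not the design. The block changed the call of 2 of 297 list tests and 19 of 245 named-gene values. The set as a covariate ended 65 of 144 named-gene calls.

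Leaving out each library in turn, the counts ranged from 5 to 29, 12 to 74, 1 to 28, 3 to 31, 6 to 18, 26 to 87, 3 to 187, 96 to 416, 0 to 5, 1 to 10, 1 to 40, 1 to 21 and 2 to 5. The number of called list tests, 112 of 297, ranged from 101 to 119; it was 28 with an estimated correlation, 85 with fry, 112 with the block, 121 with the set as a covariate and 65 within the 16-library set. There, the Th17 list in heart against NDLN Tconvs changed direction (adjusted p = 0.9), with the cause not tested. Of 245 values of named genes, 144 passed; 12 of these passed under every setting planned beforehand and 132 were lost in at least 1, and 0 changed direction. The 12 are H2-Aa in heart against spleen and NDLN Tregs and in the interaction with the NDLN, Cdkn1a in heart against NDLN Tregs, heart against spleen Tconvs and the interaction with the spleen, Foxp3 in Tregs against Tconvs of heart and spleen, and Atf3, Tnfsf11, BE692007 and Ccr8 in heart against NDLN Tconvs.

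Median-of-ratios scaling moved the median log2 fold change of all genes by over 0.1 in MLN against NDLN Tregs (0.15 to 0.28) and the interaction with the NDLN (-0.37 to -0.25). Depth limits what genes near 3 counts show, and the spread between libraries limits the rest. Of 100 simulated genes of at least 20 CPM changed 8-fold, 24 were called for heart Tregs against heart Tconvs.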

Other observations

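The levels in this part were examined after the main results had been seen.

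Summed CPM of the lists of other cell types, without TMM scaling, is given as the range over libraries in heart Tregs, lymphoid Tregs, heart Tconvs and lymphoid Tconvs, in that order. The macrophage and monocyte list ran from 764 to 1060, 114 to 680, 259 to 795 and 0.153 to 215. The CD8 and NK cell list ran from 20.7 to 46.3, 39.6 to 221, 372 to 523 and 75 to 960. The dendritic cell list, with H2-Aa, ran from 93.5 to 760, 44.8 to 2330, 44 to 1200 and 0.204 to 259. The neutrophil list ran from 75.8 to 682, 30.5 to 247, 13.5 to 239 and 0.0362 to 33.1, the endothelial list from 51.6 to 269, 27.1 to 101, 20.7 to 82 and 11.9 to 79, and the cardiomyocyte list from 15.9 to 43.2, 27.8 to 165, 9.52 to 36.5 and 7.29 to 104. Of the list members, 8 of 16 macrophage and monocyte, 7 of 9 CD8 and NK cell, 3 of 10 neutrophil, 1 of 12 endothelial, 2 of 16 cardiomyocyte, 6 of 11 dendritic cell, 7 of 12 B cell and 6 of 8 erythroid genes reached 5 CPM in some lymphoid group. The macrophage and monocyte list shares Ccr2 with the tissue homing and adhesion list.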
